A study of Mus musculus with 4 samples.

How the data were processed

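RNA-seq was measured in mouse melanocyte stem cells, the pigment cell precursors of the hair follicle, that had been purified from skin by fluorescence-activated cell sorting. The 4 libraries form 2 groups of 2. Per the labels, the control mice received saline and the stressed mice received RTX, named in the labels by this abbreviation alone, and cells were harvested 12 h after injection. Libraries were made with the Smart-Seq V4 kit from RNA isolated with the RNeasy micro kit, per the labels. The labels number the libraries within each group but do not say whether these came from separate animals, so the p-values below measure the spread between these libraries, which may be partly technical.

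The values are whole-number read counts per gene, made by the authors with featureCounts 1.6.1 per the file headers. The headers record that reads overlapping exons were summed by gene name against an mm10 annotation, with a minimum mapping quality of 30 and with neither a strand option nor a paired-end option, on alignments whose name contains the word unique. How those alignments were made unique is not given in the sources used here. The submitters' processing notes list Trim Galore 0.4.1, STAR 2.5.3, DESeq2 1.22.2 and the build mm10. Because counting was unstranded, reads from a gene and from an overlapping antisense gene cannot be told apart. Counts of near-identical copies such as Hspa1a and Hspa1b depend on how multiply aligned reads were handled and are uncertain. Per the file headers, the alignments counted for stressed replicates 1 and 2 carry the numbers 2 and 3, so the replicate numbers of the labels may differ from those of the authors.

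The files hold 27933 genes, and all 4 list the same genes. Total counts were 9273652 and 11854280 in control replicates 1 and 2, and 10625688 and 11104039 in stressed replicates 1 and 2. A count of 3, the most that a count of 0 allows, corresponds to between 0.254 and 0.321 CPM in a library. This limit covers counting error only, since reads without molecular identifiers are not independent molecules. The 2 libraries of each group differed by far more than sampling noise, with a chi-square per degree of freedom of 53.99 in the control pair and 17.99 in the stressed pair, and each was counted as 1 replicate. Coordinates are those in the files. As a check, 26604 gene symbols matched a single gene of GENCODE M21, and 99.93% of these overlapped it on the same chromosome.

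Counts were analysed in R 4.3.3. Genes were kept by edgeR's filterByExpr with its default minimum count of 10, which left 13348 genes. Libraries were scaled by TMM and the groups were compared with edgeR 4.0.16's quasi-likelihood F-test, two-sided, with group as the only term. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, with no minimum fold change. CPM, the counts scaled to a common library total, uses the TMM-scaled totals, while sums over marker lists use all counts of a library. Fold changes are fitted log2 values, stressed over control, and the standard error (SE) is the absolute log2 fold change divided by the square root of the F statistic. In all, 39 gene lists were fixed before the data were examined, and the 32 with at least 5 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists. The design, the lists, the rule for named genes and most alternatives were likewise set before the data were examined.

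The alternatives were DESeq2 size factors, upper-quartile scaling, no low-count filter beyond 1 count, a filter of at least 5 CPM in 2 libraries, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, each library left out in turn, thinning to the smallest library, removal of the 20 most abundant genes, and for lists camera with an estimated correlation and fry. When 1 library is left out, the lone library of its group is assumed to vary like the other group. Added after seeing the data were edgeR's robust quasi-likelihood fit, its likelihood ratio test, and DESeq2 with each library left out.

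Simulated data had the means and library sizes of these samples, with changes placed only in genes of at least 10 CPM. Each gene was drawn on its own, without differences shared by many genes such as those of the control pair. Recovery in the real data may therefore be lower. The edgeR test recovered 32% of genes changed by 1 log2 unit and 94% of genes changed by 2 log2 units, with 23 false calls among 149. DESeq2 recovered 52% and 97%, with 31 false calls among 180, and limma-voom recovered 34% and 94%, with 27 false calls among 155. In simulated data with no change these tools made 9, 7 and 6 calls.

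The genes named in the text were to be the 10 largest rises and 10 largest falls among called genes with an average of at least 10 CPM and non-overlapping groups, 17 genes of melanocyte, stress and cell cycle biology whatever their result, the leading members of each list, and the 5 most abundant genes. Since edgeR called no gene, the first part named none. The same rule was therefore applied to the DESeq2 calls, a choice made after the values were seen, and some further genes were also named after their values were seen. Some genes that these rules name are not reported here. In the text, "rose" and "fell" are used of a gene only where DESeq2 called it, and of a list only where camera called it.

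A further 5 lists were compiled after the values were seen and are used only among the other observations. These are lysosomal enzymes and membrane proteins, V-ATPase subunits, cytosolic aminoacyl-tRNA synthetases, upper hair follicle keratinocyte markers and genes of the major histocompatibility complex. The upper hair follicle list was first run with more members and was then cut to 11, because some had been taken from the DESeq2 calls, and 6 of those kept were such calls, so no test of this list is given.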

Results

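Gene expression was profiled in melanocyte stem cells sorted from mouse skin 12 h after injection of saline (control, n = 2) or RTX (stressed, n = 2). Going by the title of the series, the study concerns how strong activation of sympathetic nerves leads to loss of these cells. The 1 comparison the design allows is stressed against control, which asks which transcripts differ between the cells of the 2 groups. Between 9273652 and 11854280 reads were assigned to genes per library, and between 16071 and 16201 genes had at least 1 count. The most abundant transcripts by mean level included Dct, Pmel and Tyrp1, 3 pigment cell genes, together with the nuclear RNA Malat1 and the immediate early gene Fos. Dct, which encodes dopachrome tautomerase, stood at 10443 ± 943 CPM in control and 14879 ± 1479 CPM in stressed cells (SD, n = 2).

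In stressed cells, pigment synthesis genes, heat shock genes and interferon response genes lay higher than in control cells, while keratinocyte markers, immediate early genes and mitochondrially encoded mRNAs lay lower. By DESeq2, 233 genes rose and 356 fell, of which 135 and 316 changed at least 2-fold, and in all 589 both stressed libraries lay on the same side of both control libraries. The balance turned without control replicate 1, with 274 genes higher and 203 lower by DESeq2, and was 327 to 473 without control replicate 2. Such separation was found for 44.7% of all tested genes, against 33.3% expected by chance. The edgeR quasi-likelihood test called none of the 13348 genes, with a smallest adjusted p of 0.115, although 690 genes were higher and 1015 lower at an unadjusted p below 0.05. With limma-voom there were likewise 0 calls, with 1700 genes at an unadjusted p below 0.05. The edgeR count was 760 with no low-count filter, 628 without control replicate 1 (305 higher, 323 lower) and 739 without control replicate 2 (226 higher, 513 lower), and the DESeq2 count was 144 without stressed replicate 1 and 47 without stressed replicate 2. Of the 589 genes, DESeq2 again called 285 without control replicate 1, 401 without control replicate 2, 130 without stressed replicate 1 and 45 without stressed replicate 2.

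The control libraries were the less alike pair. Pearson's correlation of log2 CPM across genes, which are not independent replicates, was 0.927 between the controls, 0.962 between the stressed libraries, and between 0.919 and 0.936 across groups. In the control pair 1852 genes were more than 2-fold apart, against 1095 in the stressed pair. The first principal component held 45.3% of the variance and separated the groups, while the second held 36.1% and set control replicate 2 at -59.91 against 31.12 for control replicate 1. Control replicate 1 had more keratinocyte marker RNA, at 32980 CPM summed over 17 genes against 19080 in control replicate 2. Control replicate 2 had a larger mitochondrial share, at 2.07% of counts against 0.906%. The stressed libraries had 12550 and 10650 CPM of keratinocyte markers and mitochondrial shares of 0.479% and 0.405%.

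Genes of pigment synthesis and the melanosome rose together. All 16 members of the list were higher in stressed cells, with a median log2 fold change of 0.82, and in 14 both stressed libraries exceeded both controls. Tyrp1 (chromosome 4, 80834123-80851719, mm10), which encodes an enzyme of eumelanin synthesis, rose by DESeq2 from 2955 ± 233 to 7598 ± 30 CPM (SD, n = 2), a log2 fold change of 1.36 with an SE of 0.25. Gpnmb (chromosome 6, 49036546-49070929), which encodes a melanosomal glycoprotein, rose from 2465 ± 239 to 6822 ± 364 CPM. Pmel (chromosome 10, 128706258-128720238), the source of melanosome fibrils, rose from 3879 ± 1478 to 9224 ± 578 CPM. Oca2, a melanosome membrane transporter gene, rose from 16.2 ± 3.4 to 72.4 ± 38.1 CPM. Tyr, which encodes the rate-limiting enzyme tyrosinase, was at 620 ± 160 and 1028 ± 95 CPM and was not called by DESeq2 or edgeR over all genes. Camera called the list at an adjusted p of 1.76e-13, and the adjusted p = 0.36 with an estimated correlation. No member passed edgeR over all genes, 10 did when adjusted over the list alone, and DESeq2 called 6. Keratinocyte marker RNA was lower in both stressed libraries, as given above.

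Other lists of pigment cell genes had smaller medians. The melanosome transport list rose with a median log2 fold change of 0.31 and 14 of 16 members higher (camera adjusted p = 0.0024, and adjusted p = 0.36 with an estimated correlation). Its member Myo5a, which encodes the motor that holds melanosomes at the cell periphery, rose by DESeq2 from 991 ± 91 to 1671 ± 169 CPM. The 16 melanocyte lineage regulators were not called as a list (median 0.14, camera adjusted p = 0.145). Without control replicate 2 the list was called higher (median 0.41, adjusted p = 0.0307), and without control replicate 1 its median was -0.028. Among them Kit (chromosome 5, 75574916-75656722), the receptor for stem cell factor, rose by DESeq2 from 1844 ± 47 to 2984 ± 451 CPM, with a log2 fold change of 0.69 and an SE of 0.24. Mitf, the master transcription factor of the lineage, was at 372 ± 113 and 430 ± 32 CPM, and Sox10 at 690 ± 283 and 729 ± 63 CPM. Ednrb, the endothelin receptor gene of the lineage, was level at 1207 ± 52 and 1203 ± 92 CPM. The Mitf and Sox10 differences were smaller than their SEs of 0.26 and 0.31, and the survival gene Bcl2 differed by 0.23 with an SE of 0.24. The sign of the Mitf difference turned without control replicate 2, and those of Sox10 and Bcl2 turned without control replicate 1.

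**Figure D1:**
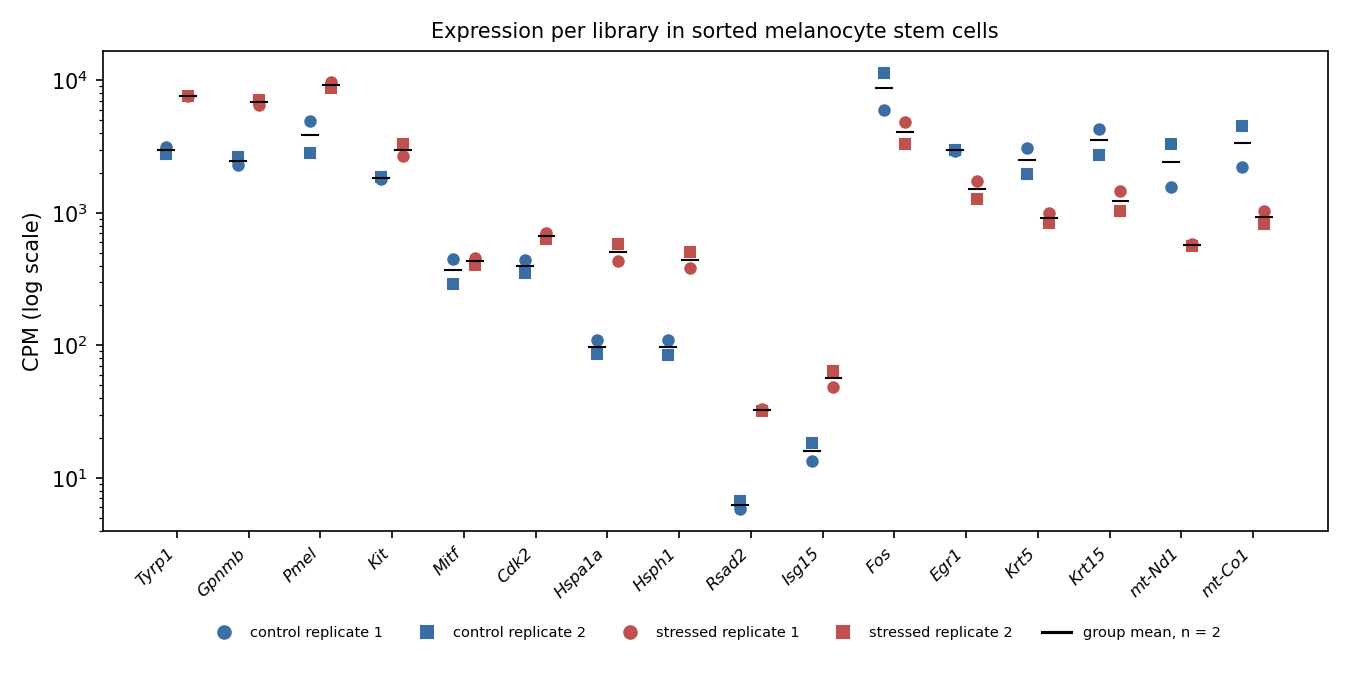
CPM on a log scale in each of the 4 libraries for 16 genes, with circles and squares for replicates 1 and 2 and a black bar for each group mean (n = 2). Tyrp1 stands at 2955 CPM on average in control and 7598 CPM in stressed cells, while Mitf overlaps between groups and Fos and the mitochondrial genes differ widely between the 2 controls.

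Heat shock genes rose with the smallest camera p of the fixed lists. Of 13 members 12 were higher, with a median log2 fold change of 0.77, and 11 were higher in both stressed libraries than in both controls. Hspa1a (chromosome 17, 34969190-34972156), which encodes the inducible chaperone HSP70, rose by DESeq2 from 97.6 ± 16.6 to 508 ± 110 CPM, a log2 fold change of 2.38 with an SE of 0.25 and an edgeR adjusted p of 0.115. Its near-identical neighbour Hspa1b rose from 253 ± 77 to 1000 ± 114 CPM by DESeq2, and the split of reads between the pair is uncertain. Hsph1, which encodes an HSP110 chaperone, rose from 97.5 ± 17.8 to 443 ± 85 CPM. Hsp90aa1 rose from 189 ± 22 to 417 ± 38 CPM, whereas Dnajb1, a co-chaperone gene, was at 415 ± 130 in control and 313 ± 71 CPM in stressed cells. The list had a camera adjusted p of 8.75e-16, and an adjusted p = 0.36 with an estimated correlation. No member passed edgeR over all genes, 8 did when adjusted over the list alone, and DESeq2 called 7.

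Smaller shifts were seen in other stress lists. The unfolded protein response rose with a median of 0.33 and 14 of 17 members higher (camera adjusted p = 0.0011, and adjusted p = 0.36 with an estimated correlation). Its only DESeq2 call was Asns, the asparagine synthetase gene, at 39.6 ± 10.2 and 77.8 ± 13.7 CPM. The p53 list rose with a median of 0.24 and 15 of 20 members higher (camera adjusted p = 0.0127, and adjusted p = 0.36 with an estimated correlation). Gdf15, a secreted stress factor gene, rose by DESeq2 from 0.894 ± 0.053 to 8.98 ± 2.03 CPM, and Bax, which encodes a pro-apoptotic pore protein, rose from 60.0 ± 6.0 to 113 ± 15 CPM. Cdkn1a, which encodes the cell cycle inhibitor p21, was at 336 ± 80 and 280 ± 16 CPM and was not called by either tool. Perp, a desmosome gene that is also among the keratinocyte markers, fell by DESeq2 from 1996 ± 1072 to 948 ± 151 CPM, with a log2 fold change of -1.07 that was -0.37 without control replicate 1. The oxidative stress list rose by a median of 0.21 (camera adjusted p = 0.0388, and adjusted p = 0.36 with an estimated correlation). Its members Srxn1 and Txnrd1, which encode sulfiredoxin and a thioredoxin reductase, rose by 1.71 and 0.93 by DESeq2. The glycolysis and hypoxia list rose by a median of 0.43 (camera adjusted p = 0.0238, and adjusted p = 0.49 with an estimated correlation). In it Gapdh rose from 149 ± 6 to 236 ± 17 CPM, while Pdk1, which encodes an inhibitor of pyruvate dehydrogenase, had a value of -0.85 that was not called by DESeq2. Without control replicate 2 the calls of the unfolded protein, p53 and oxidative stress lists were lost, at adjusted p values of 0.0636, 0.471 and 0.265, the last with a median of 0.11 and also lost with the filter of at least 5 CPM, at 0.0513. Without control replicate 1 the unfolded protein and p53 medians were 0.63 and 0.47. The glycolysis call was lost without control replicate 1 and without stressed replicate 2, at 0.316 and 0.149.

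Interferon response genes rose with the largest median of the lists that rose, 1.17, and 18 of 20 members were higher. Rsad2 (chromosome 12, 26442753-26456452), which encodes the antiviral protein viperin, rose by DESeq2 from 6.24 ± 0.64 to 32.5 ± 1.1 CPM, and Isg15 rose from 15.9 ± 3.4 to 56.6 ± 11.3 CPM. Psmb9, which encodes a subunit of the immunoproteasome, fell from 35.6 ± 8.8 to 16.4 ± 1.7 CPM. The camera adjusted p was 2.05e-12, and the adjusted p = 0.36 with an estimated correlation. Adjusted over the list alone, 8 members were higher and 1 was lower by edgeR, and DESeq2 called 6 and 1. The list's median was 0.70 without control replicate 1 and 1.84 without control replicate 2, and control replicate 2 lay above control replicate 1 by a median of 0.938 log2 units in these genes.

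Immediate early genes, the first transcripts induced by signals at the cell surface, fell as a list. Of 22 members 20 were lower, with a median of -0.74, and 13 were lower in both stressed libraries than in both controls. Fos (chromosome 12, 85473890-85477273) fell by DESeq2 from 8679 ± 3835 to 4081 ± 1067 CPM, with a log2 fold change of -1.09 that was -0.55 without control replicate 2. Ier2 fell from 833 ± 93 to 396 ± 75 CPM, Egr2 from 428 ± 85 to 224 ± 35 CPM and Dusp1, a MAP kinase phosphatase gene, from 923 ± 19 to 449 ± 158 CPM. The camera adjusted p was 4.94e-07, and the adjusted p = 0.38 with an estimated correlation. By edgeR 6 members were lower when adjusted over the list alone, and DESeq2 called 8. The summed list stood at 21800 and 37070 CPM in control replicates 1 and 2, and without control replicate 2 the median was -0.42.

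Genes tied to the hormones and transmitters of stress moved in different directions. The cAMP and CREB list rose with a median of 0.27 and 15 of 20 members higher (camera adjusted p = 0.00227, and adjusted p = 0.36 with an estimated correlation). Its DESeq2 calls were the orphan receptor gene Nr4a2, from 15.8 ± 6.5 to 38.1 ± 0.3 CPM, and the phosphodiesterase gene Pde4d, from 18.6 ± 0.1 to 43.9 ± 14.0 CPM. The list's median was 0.43 without control replicate 1 and 0.054 without stressed replicate 1. Crem, a cAMP-responsive transcription factor gene, was at 27.1 ± 4.1 and 43.7 ± 7.5 CPM, and Nr4a1 at 743 ± 217 and 869 ± 170 CPM, neither called by DESeq2 or edgeR. Nr4a1 was at 0.23 on the log2 scale and its sign turned without control replicate 2. All 8 tested receptors of stress mediators were lower, with a median of -0.85 (camera adjusted p = 0.0132, and adjusted p = 0.36 with an estimated correlation). Nr3c1, the glucocorticoid receptor, was at 184 ± 44 and 170 ± 2 CPM, and its sign turned without control replicate 2. Trpv1, the capsaicin receptor gene, was close to the floor, with 15 and 17 counts in the controls and 6 and 3 in the stressed libraries. The receptor call was lost without control replicate 2 and without stressed replicate 2, at adjusted p values of 0.345 and 0.263 with medians of -0.49 and -0.39, and with no low-count filter, at 0.0657 with a median of -1.51.

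The glucocorticoid response list was not called (median -0.41, camera adjusted p = 0.125), and its controls differed. It was called lower without control replicate 1 (median -0.62, adjusted p = 4.37e-08) and without stressed replicate 1 (median -0.52, adjusted p = 0.00291). Without control replicate 2 its direction turned, with a median of 0.40 and an adjusted p of 0.147. Fkbp5, a co-chaperone gene of the glucocorticoid receptor, was at 9.96 and 63.0 CPM in control replicates 1 and 2, and at 23.3 and 25.3 CPM in stressed replicates 1 and 2. Its log2 difference of -0.59 had an SE of 0.73 and became 1.29 without control replicate 2. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, was at 208 and 493 CPM in the controls and at 424 and 250 CPM in the stressed libraries.

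Among cell cycle genes, those of G2 and mitosis rose as a list. Of 26 members 25 were higher, with a median of 0.62, but Bub1b, a spindle checkpoint kinase gene, was the 1 DESeq2 call, at 34.5 ± 13.3 in control and 78.7 ± 22.0 CPM in stressed cells. Mki67 was at 90.7 ± 30.2 and 122 ± 21 CPM and was not called. The camera adjusted p was 4.1e-08, and the adjusted p = 0.49 with an estimated correlation. The list's median was 0.21 without control replicate 2, with the call lost at 0.0703, 0.39 without stressed replicate 1, and 1.17 without control replicate 1. The S phase list was not called (median 0.14, camera adjusted p = 0.254). Its median lay between 0.038 and 0.24 with 1 library left out. Cdk2 (chromosome 10, 128697939-128705051), a cyclin-dependent kinase gene that lies 1206 bp from Pmel on the opposite strand, rose by DESeq2 from 396 ± 66 to 671 ± 51 CPM, with a log2 fold change of 0.76 and an SE of 0.22. Ccnd1 was at 18.5 ± 16.1 and 27.3 ± 0.3 CPM, and its sign turned without control replicate 2. The list of cyclins and kinases was not called, and its median of -0.01, its mean of -0.11 and the direction given by camera, higher, did not share a sign. That direction turned without control replicate 2 and without stressed replicate 2, with medians of -0.11 and -0.095.

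Keratinocyte markers fell as a list. All 17 had lower values in stressed cells, with a median of -1.08, and 13 were lower in both stressed libraries than in both controls. Krt5 (chromosome 15, 101707070-101712891), a keratin gene of basal keratinocytes, fell by DESeq2 from 2526 ± 817 to 917 ± 119 CPM, with a log2 fold change of -1.46 and an SE of 0.30. Krt15, expressed by keratinocytes of the follicle bulge, fell from 3520 ± 1141 to 1238 ± 303 CPM, and Krt79, of the upper follicle, from 2672 ± 36 to 1163 ± 92 CPM. The camera adjusted p was 1.35e-12, and the adjusted p = 0.36 with an estimated correlation. By edgeR 8 members were lower when adjusted over the list alone, and DESeq2 called 9. The desmosomal cadherin gene Dsg3 was level, at 79.7 ± 7.1 and 79.5 ± 28.3 CPM. The keratinocyte list's median was -0.54 without control replicate 1 and -1.34 without control replicate 2. The list of hair follicle stem and germ cell markers, which shares Krt15, was not called (median -0.16, camera adjusted p = 0.084). It was called lower without control replicate 1 (median -0.29) and without stressed replicate 1 (median -0.62), while its median was -0.044 without control replicate 2. Its transcription factor genes Sox9 and Nfatc1 were at 122 ± 5 and 185 ± 4 CPM in control and at 117 ± 54 and 167 ± 11 CPM in stressed cells.

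Markers of most other skin cells were scarce, apart from the Schwann cell and nerve list, which summed to 1153 and 1698 CPM in the controls and 1422 and 1204 CPM in the stressed libraries. Macrophage and dendritic markers summed to 110.8 CPM in control replicate 2 and to between 15.7 and 25.9 CPM in the other 3 libraries. The list fell by a median of -1.95 (camera adjusted p = 0.0238, and adjusted p = 0.57 with an estimated correlation), and the call was lost without control replicate 2, at 0.985 with a median of -0.30, and with limma-voom, at 0.0713. The median was -5.95 without stressed replicate 2. H2-Ab1, an MHC class II gene, fell by DESeq2 and stood at 9.86 and 49.0 CPM in the controls and 3.10 and 5.46 CPM in the stressed libraries, with a log2 fold change of -2.78 that was -1.20 without control replicate 2. The pericyte list rose by a median of 0.77 over 6 tested genes (camera adjusted p = 0.0388, and adjusted p = 0.36 with an estimated correlation), and the call was lost without either control, at 0.158 without control replicate 1, where the median was -0.025, and 0.147 without control replicate 2. It was also lost with no low-count filter, with limma-voom and with thinning, at 0.0528, 0.114 and 0.0579. The median was 0.41 without stressed replicate 1. Its DESeq2 call was Cspg4, a proteoglycan gene that is also known from melanocytic cells, at 69.0 ± 7.1 and 206 ± 63 CPM. Fibroblast and Schwann cell lists were not called, at camera adjusted p values of 0.945 and 0.167, and the fibroblast median of 0.26 was opposite in sign to its mean of -0.16 and to camera's direction, lower. The fibroblast list was called higher without stressed replicate 2 (median 0.82, adjusted p = 0.0038), and its median was -1.31 without stressed replicate 1 and 0.91 without control replicate 1. The Schwann cell list was called lower without control replicate 1 (median -0.39), and its median was 0.24 without control replicate 2 and -0.70 without stressed replicate 2. Endothelial, mast cell, neutrophil, T and B cell, adipocyte, muscle and red blood cell lists had fewer than 5 tested genes. Their summed markers reached at most 19.3, 6.15, 126.7, 1.94, 58.9, 12.5 and 1.83 CPM in any library.

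Mitochondrially encoded mRNAs fell as a group. All 8 tested genes were lower in both stressed libraries than in both controls, with a median of -1.70. The complex I gene mt-Nd1 (mitochondrial genome, 2751-3707) fell by DESeq2 from 2434 ± 1239 to 573 ± 18 CPM, and the complex IV gene mt-Co1 fell from 3393 ± 1645 to 926 ± 147 CPM. The camera adjusted p was 4.04e-12, and the adjusted p = 0.36 with an estimated correlation. By edgeR all 8 were lower when adjusted over the list alone, and DESeq2 called 7. Without control replicate 2, which had the largest mitochondrial share, the median was -0.95. The 82 nuclear genes of oxidative phosphorylation were not called (median -0.05, camera adjusted p = 0.582), and neither were the 77 ribosomal protein genes (median 0.10, camera adjusted p = 0.0617). The ribosomal list was called higher without control replicate 1 (median 0.37, adjusted p = 1.92e-08) and without stressed replicate 2 (median 0.13, adjusted p = 0.0207), and turned to a median of -0.13 without control replicate 2. The nuclear oxidative phosphorylation list was then called lower (median -0.18, adjusted p = 0.0307), and its median was 0.10 without control replicate 1.

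Genes of migration and mesenchymal character rose with a median of 0.47 and 14 of 17 members higher (camera adjusted p = 2.76e-06, and adjusted p = 0.36 with an estimated correlation). Fn1, the fibronectin gene, rose by DESeq2 from 3.65 ± 0.14 to 32.3 ± 18.1 CPM, and Vim, the intermediate filament gene vimentin, from 1476 ± 128 to 2820 ± 634 CPM. Cxcr2, a chemokine receptor gene, had 0 counts in the controls and 69 and 39 counts in the stressed libraries, at least 17.4-fold higher against a floor of 3 counts per control library. With Cxcr2 at that bound the list's median remained 0.47. Cxcr2 is also a neutrophil marker, and the summed neutrophil markers stood at 55.0 and 6.92 CPM in the controls and at 126.7 and 9.64 CPM in the stressed libraries. Among these Ltf, the lactoferrin gene, was at 49.7 and 0 CPM in control replicates 1 and 2 and at 112 and 0.727 CPM in stressed replicates 1 and 2. The Notch list fell by a median of -0.25 with 11 of 13 members lower (camera adjusted p = 0.0172, and adjusted p = 0.36 with an estimated correlation), a call lost without control replicate 2 at 0.113, and its median was -0.59 without control replicate 1. Its ligand gene Jag2 fell by DESeq2 from 125 ± 11 to 55.4 ± 2.5 CPM.

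The largest DESeq2 rises among genes averaging at least 10 CPM were in Acvr1c, a receptor gene of the TGF-beta family, from 1.12 ± 0.39 to 20.7 ± 4.8 CPM, and in Slc24a4, a sodium-calcium exchanger gene, from 3.30 ± 2.75 to 59.9 ± 29.4 CPM. These were followed by the sphingosine phosphate receptor gene S1pr3, from 5.57 ± 2.43 to 63.4 ± 42.1 CPM, and included Angptl4, from 20.96 ± 9.18 to 110.5 ± 0.7 CPM, and Fbln5, a matrix protein gene, from 13.4 ± 5.3 to 66.9 ± 10.8 CPM. The largest falls were in Akr1c18, which encodes a progesterone-metabolizing enzyme, from 57.1 ± 15.1 to 3.39 ± 1.97 CPM, and Sprr4, a cornified envelope gene, from 29.9 ± 6.3 to 3.77 ± 1.61 CPM. Tchh, which encodes the hair sheath protein trichohyalin, fell from 27.0 ± 0.6 to 5.04 ± 0.70 CPM. The edgeR adjusted p of these genes lay at 0.115 or above.

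**Figure D2:**
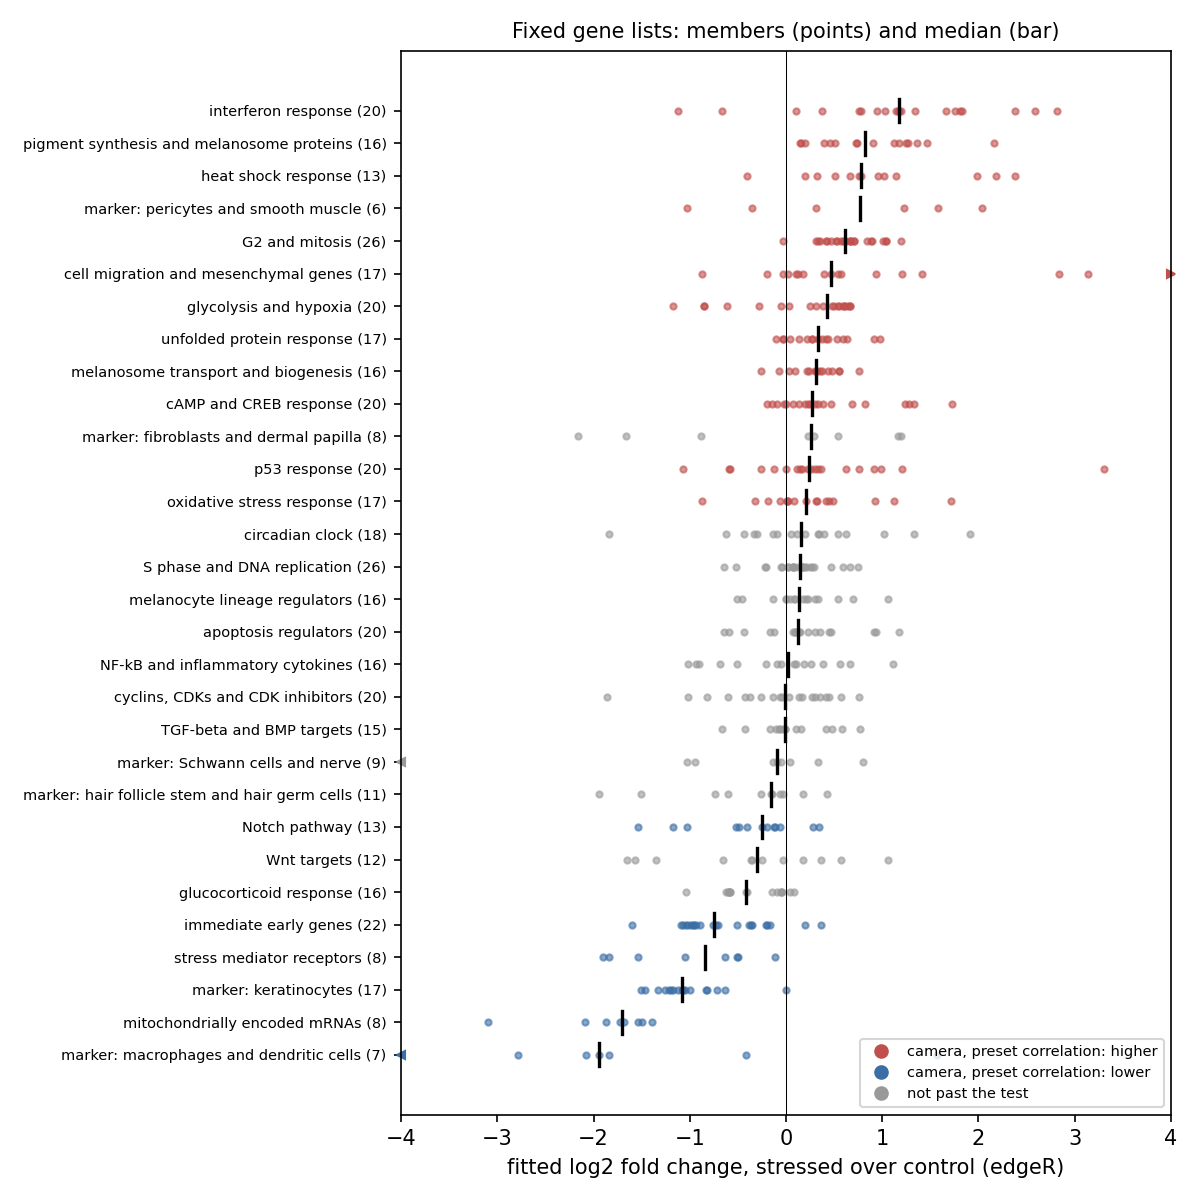
Fitted log2 fold changes, stressed over control, of the members (points) of 30 fixed gene lists with at least 5 tested genes, with the number of genes drawn beside each name and a black bar at the list median. Red and blue mark lists that camera called higher or lower at its preset correlation, grey marks lists not called, and 3 members beyond 4 in either direction are drawn as arrows at the edge. Interferon, pigment and heat shock medians lie at 1.17, 0.82 and 0.77, and keratinocyte and mitochondrial medians at -1.08 and -1.70.

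In all, camera called 12 lists higher and 6 lower of 32 tested, while 0 passed with an estimated correlation, where the smallest adjusted p was 0.359, and 0 passed by fry, where it was 0.104 and 9 lists had an unadjusted p below 0.05. The apoptosis, NF-kB, circadian clock, TGF-beta and Wnt lists were not called, with medians of 0.13, 0.02, 0.15, -0.01 and -0.30. With 1 library left out, medians ran from 0.15 to 0.27 for apoptosis, 0.15 to 0.35 for the circadian clock and -0.37 to -0.11 for Wnt. The NF-kB mean of -0.07 was opposite in sign to its median, and the TGF-beta mean of 0.06 was opposite to its median. Camera's direction turned for the NF-kB list without stressed replicate 1, where the median was -0.41, and for the TGF-beta list without control replicate 1, where it was -0.048. In these lists DESeq2 called Bid, a pro-apoptotic gene, which rose from 10.4 ± 0.6 to 23.4 ± 1.3 CPM, and Id3, a target gene of BMP signals, which rose from 224 ± 42 to 383 ± 35 CPM. It also called Rnf43, a Wnt feedback inhibitor gene, which fell from 33.5 ± 8.1 to 11.3 ± 2.4 CPM, and Apcdd1, which fell from 91.1 ± 49.0 to 29.1 ± 16.4 CPM, with a log2 fold change of -1.65 that was -0.95 without control replicate 1.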

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

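The robust edgeR fit, the edgeR likelihood ratio test and DESeq2 with libraries left out were chosen after the data were seen. The count of 0 genes called by edgeR stood under both scaling alternatives, the filter of at least 5 CPM, limma-voom, thinning, removal of the 20 most abundant genes and the robust fit. It became 760 genes with no low-count filter, 589 by the DESeq2 Wald test and 549 by the likelihood ratio test, and for genes changed at least 2-fold 608, 451 and 453. Leaving out 1 library gave between 0 and 739 calls, and between 0 and 669 at 2-fold. Of the 760, 543 were among the DESeq2 calls. The DESeq2 count lay between 47 and 800 with 1 library left out. The cause of the differences between tests and filters was not tested. Fewer libraries entered the fits with 1 left out, and these take their spread from the intact pair alone. The SD of the log2 differences was 0.8821 in the control pair and 0.6543 in the stressed pair. Counts without a control library, which rest on the closer stressed pair, are therefore not comparable with counts without a stressed library. Fits with the replicate number as a block called 0 genes, 0 at 2-fold and 19 lists. The numbers are not known to mark shared animals, and the deviations of same-numbered libraries correlated at 0.172 over 2 pairs.

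The number of lists called by camera, 18, was 0 with an estimated correlation and 0 by fry. Under all other settings it lay between 12 and 20. The estimate lay above the preset 0.01 for some called lists, such as the mitochondrial list at 0.962. For others it lay below, such as Notch at -0.0687 and melanosome transport at -0.0407, and these calls were lost too. A larger correlation is thus not the reason in those lists. With an estimated correlation camera also takes its degrees of freedom from the 4 libraries, whereas at a preset correlation it takes them from the number of genes. With so few libraries hardly any list can pass, so its adjusted p says little about a single list. How far this accounts for each lost call was not tested. Adjusted p for the 18 lists ranged up to 0.985 (macrophage list, without control replicate 2), and for the pigment and heat shock lists from 7e-21 and 5.03e-21 to 0.36. Of the list values under alternatives 195 kept their call and 54 lost it, of which 18 each came from the estimated correlation and from fry and the others are given with each list. Of the lists not called, camera called hair follicle stem and germ cell markers lower with the block (median -0.23, adjusted p = 0.0362), and ribosomal proteins higher with no low-count filter (0.0407) and with limma-voom (0.019). Such calls with 1 library left out are given with each list.

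The log2 difference turned under at least 1 alternative for 14 named genes, none of them called by edgeR or DESeq2 with all libraries. Values with 1 library left out ran from -0.068 to 0.57 for Mitf, -0.27 to 0.58 for Sox10, -0.33 to 0.16 for Nr3c1, -0.13 to 1.95 for Ccnd1, -0.018 to 0.55 for Bcl2 and -0.042 to 0.57 for Nr4a1. They ran from -1.36 to 1.29 for Fkbp5, -1.33 to 1.09 for Klf9, -0.53 to 0.70 for Tsc22d3, -0.42 to 0.33 for Dsg3, -0.080 to 0.081 for Ednrb, -0.62 to 0.36 for Sox9 and -0.48 to 0.013 for Cdkn1a. For Ltf, absent or nearly so from 1 library of each group, the value was -5.06 without stressed replicate 1. It was 12.31 without control replicate 1, where the remaining control library stood at 0 CPM. With all libraries Tsc22d3 also turned with limma-voom (0.036) and with the block (0.023). Dsg3 and Ednrb turned with DESeq2 size factors (0.0023 and 0.0022), the Wald test (0.0024 and 0.0022) and without the 20 most abundant genes (0.0025 and 0.0015). The cause was not tested. Since genes were named partly after their values were seen, this is not a share of all genes. For Tyrp1 and Hspa1a, log2 fold changes lay within 1.29 to 1.46 and 2.15 to 2.59 over all alternatives, with adjusted p from 1.18e-10 to 0.799 and from 5.66e-17 to 0.671. Library correlations moved little with the filter of at least 5 CPM, at 0.913 for the controls and 0.964 for the stressed pair. With 2 libraries a group the edgeR test recovered 32% of simulated changes of 1 log2 unit in genes of at least 10 CPM. Each simulated gene was drawn on its own, so recovery in the real data may be lower.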

Other observations

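The lists, the tests and the bounds for judging them in this part were all set after the values were seen. All 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for translation, were higher in stressed cells, with a median log2 fold change of 0.36 at percentile 100 of 10000 random lists matched on expression. The random lists do not keep genes that move together, so percentiles given here cannot tell the treatment from other differences between libraries. Aars and Iars rose by DESeq2 from 155 ± 6 to 299 ± 73 CPM and from 133 ± 21 to 248 ± 30 CPM, and so did Slc7a5, an amino acid transporter gene, from 240 ± 24 to 479 ± 14 CPM. Of 20 tested V-ATPase subunits, which acidify lysosomes and melanosomes, 16 were higher (median 0.22, at percentile 97.9), with 3 members rising and 2 falling by DESeq2. Atp6v1b2 rose from 447 ± 26 to 818 ± 23 CPM, while Atp6v1c2 and Atp6v0a4 fell from 54.4 ± 19.0 to 19.6 ± 0.6 CPM and from 23.3 ± 0.3 to 8.70 ± 1.11 CPM. Of 45 lysosomal genes 30 were higher (median 0.15, at percentile 91.5), with 9 DESeq2 calls, among them Hexa, from 156 ± 0.3 to 301 ± 6 CPM, and Cd63, from 929 ± 62 to 1529 ± 10 CPM. With a preset correlation camera gave these lists adjusted p values of 8.93e-07, 0.0193 and 2.74e-05, and with an estimated correlation the adjusted p was 0.24, 0.33 and 0.17. The V-ATPase call was lost without control replicate 2 and without stressed replicate 1, at 0.28 and 0.072, and its median was 0.40 without control replicate 1. The lysosomal median lay between 0.19 and 0.26 with 1 library left out, with the highest value without control replicate 1.

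Of 11 upper hair follicle markers 8 were lower, with a median of -1.12, but 6 were DESeq2 calls seen before the list was drawn up, so no test of it is given. Lrig1 fell by DESeq2 from 221 ± 57 to 72.6 ± 7.1 CPM, Gata6 from 38.2 ± 6.9 to 9.65 ± 0.63 CPM and Sostdc1 from 313 ± 93 to 86.3 ± 15.9 CPM. Krt6b, a keratin gene of the inner follicle and of activated keratinocytes, had 0 counts in the controls and 197 and 149 in the stressed libraries, at least 55.7-fold higher against a floor of 3 counts per control library. The inner root sheath keratin genes Krt71 and Krt25 rose from 3.52 ± 4.37 to 23.2 ± 1.8 CPM and from 2.67 ± 2.57 to 14.4 ± 2.2 CPM. Their log2 values of 2.68 and 2.40 were 5.72 and 4.05 without control replicate 2, and at lowest 1.82 and 1.69 over all alternatives. In contrast the hair sheath gene Tchh fell, from 27.0 ± 0.6 to 5.04 ± 0.70 CPM. Of 16 tested MHC genes 14 were lower, with a median of -1.08 (camera adjusted p = 2.74e-05, and adjusted p = 0.24 with an estimated correlation), and H2-K1 fell from 1462 ± 317 to 820 ± 36 CPM while interferon response genes were higher. The MHC median was -0.59 without control replicate 2, the library in which macrophage and dendritic markers summed to 110.8 CPM against 15.7 to 25.9 CPM elsewhere.

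Pigment genes rose while keratinocyte markers fell. A smaller share of keratinocytes in the stressed libraries, despite the sort, would raise all genes of the pigment cell alike. The mean of the 16 pigment genes exceeded that of 8 genes of the melanocyte lineage, among them Kit, Sox10 and Mitf, by 0.718 log2 units (exact two-sided permutation p = 0.00262 over genes, which are not independent), and by 0.43 to 1.04 with 1 library left out. Per library this difference was -0.461 and -1.07 in the controls and -0.105 and 0.0122 in the stressed libraries, without overlap but with the controls nearly as far apart as the group means, so a smaller share of keratinocytes cannot be told apart from other sources of the pigment rise. For the keratinocyte markers themselves a smaller share cannot be told apart from other sources. The SD of their log2 fold changes, 0.36, was 1.084 times their median SE. That SE includes the difference between the 2 controls, which these genes shared in part (estimated correlation 0.505), so the ratio cannot decide. Single genes were not all alike, with Dsg3 at -0.004 (SE 0.27) and Krt79 at -1.20 (SE 0.22). The stress treatment stays open as untested.

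Mitochondrially encoded mRNAs fell in stressed cells. Without control replicate 2 the median was -0.9537, but that fit leaves 1 control library, so its tests cannot decide. All 8 genes were also lower in both stressed libraries than in control replicate 1. Its mitochondrial share was 0.906% against 0.479% and 0.405% in the stressed libraries. The fall was thus not confined to control replicate 2, though this comparison rests on 1 control library. The mean of the mitochondrially encoded mRNAs minus that of the keratinocyte markers was -0.8332 (exact two-sided permutation p = 5.55e-06 over genes). These genes are not independent, with estimated correlations of 0.962 and 0.505 within the 2 lists, so this p overstates the evidence. The difference in means was 0.33 without control replicate 2 and -1.77 without control replicate 1. A smaller share of keratinocytes cannot be told apart from other sources, as the deciding difference rests on 1 control library. An effect of the treatment was not tested separately.

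Immediate early genes fell while heat shock genes rose. A weaker response to dissociation and sorting, which induces both, cannot be told apart from other sources: the heat shock median was 0.774, and between 0.66 and 1.03 with 1 library left out, but another source may have raised these genes. A smaller share of keratinocytes cannot be told apart either. In the control pair the immediate early median was 0.3826 higher in replicate 2 than in replicate 1 where keratinocyte markers were lower by -0.67, whereas in the stressed pair both were lower in replicate 2, by -0.38 and -0.33. An effect of the stress treatment stays open as untested.

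The 589 DESeq2 calls came from 1 of 3 ways to split the 4 libraries into 2 and 2, and the highest count of the other splits was 35. With 3 splits a share below 0.05 cannot be reached.

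Of 16 tested glucocorticoid response genes 11 had their highest level in control replicate 2, against 25.3% of all tested genes. Klf9, a target gene of glucocorticoids, stood at 98.4 and 528 CPM in the controls and at 228 and 191 CPM in the stressed libraries. Jun stood at 1840 and 6790 CPM in the controls and at 1543 and 1293 CPM in the stressed libraries. Xist, the RNA of the inactive X chromosome, fell by DESeq2 from 191 ± 7 to 82.2 ± 12.1 CPM, and Y-linked genes other than Erdr1 had 0, 0, 1 and 0 counts in the 4 libraries.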
